A study of Homo sapiens with 5 samples.

How the data were processed

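Total RNA from 5 samples of the human glioma cell line D54 was measured on Affymetrix whole-transcript expression arrays, 1 array per sample. Per the labels, RNA was taken from cells that were trypsinised, seeded and grown overnight, and labelled single-stranded cDNA was hybridised. The series' design text states that the arrays were processed by the authors with the Affymetrix Exon Array Computational Tool. Its version, the background correction, the summary of probes into transcripts and the normalization are not given in the sources used here. The design text names the exon version of the array, but the row identifiers matched the annotation of the gene-level version (Human Gene ST), so the values were read as 1 value per transcript cluster and no exon was compared.

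The deposited values are log2 signals, as the authors left them. They ran from 3.27 to 14.7, and the array medians lay between 7.88 and 7.98. Upper quartiles lay between 9.77 and 9.83. Because these quantiles nearly coincided, the values were taken as already normalized and used as deposited. They were still ordered by group. Lower quartiles were 6.45 and 6.44 in the controls and 6.42, 6.40 and 6.35 in shRNAs 1, 2 and 3. Upper quartiles were 9.77 and 9.77 against 9.79, 9.80 and 9.83. Dim rows thus tended to be lower and bright rows higher with TIP-1 shRNA, which bears on small differences and on counts of rows by direction. The table holds no detection call and no background signal, so a dim row could not be called absent. The number of arrays, 2 against 3, limits the precision.

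All 33297 rows were tested. Of these, 19460 had 1 gene symbol, 1754 had several and 12083 had none in the annotation used, which can be old. Symbols were looked up through the gene identifier for 19429 of the single-symbol rows, in a gene table of assembly GRCh38.p14, and none changed. No genome build is stated for the arrays, so no coordinates are given, and that table served only for names and for which genes are neighbours. Genes were named only from rows with 1 symbol, apart from the row of the silenced gene, which also carries the symbol of a read-through transcript. For gene lists, the row with the highest mean over all 5 arrays stood for each of 18417 genes.

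The groups were 2 control shRNA arrays and 3 TIP-1 shRNA arrays. Per the labels, the controls were independent clones and each TIP-1 array came from a different shRNA, with no technical replicates. The p-values therefore measure the spread between clones and between shRNAs. Differences are TIP-1 shRNA minus control shRNA in log2 units. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all rows and a threshold of 0.05. Intervals are limma's 95% intervals. With 2 arrays against 3, an exact permutation test of a single gene on the absolute difference cannot go below a p of 0.1, so none was used.

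The test was checked on 10 simulated data sets with the real row means and 200 changed rows each. In the same sets, the rows of the cell cycle list were also raised by 0.2 log2 units in the TIP-1 shRNA arrays. The spread of all rows was drawn from a fit of the same model to the real values. For this comparison, it recovered 6.4% of rows changed by 0.5 log2 units, 63.4% of those changed by 1, 95.6% of those changed by 2 and 98.8% of those changed by 3. It made on average 4.7 false calls per set outside the changed rows and that list. Rows were drawn independently of each other, so this count does not cover structure shared across rows. These rates hold for sets with 200 changed rows. With fewer changed rows the Benjamini-Hochberg cut-off is stricter, so a smaller share would be recovered. In the real values, 55 rows differed by at least 1 log2 unit and 1 of them was called.

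Before the data were examined, 31 gene lists were written from textbook knowledge, covering partners of TIP-1, the cytoskeleton, Wnt targets, matrix and adhesion, proteases, growth, stress and metabolism, glioma subtypes and other cell types. Of 851 listed symbols, 788 matched a row, some through older names. The rest were not analysed here. All 31 entered the adjustment, but the results of 2 lists are not reported here. Lists were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera was repeated with a correlation estimated for each list, and fry was run beside it, which asks whether a list's genes move on balance in 1 direction or, in its mixed form, in either. Overlaps between shRNAs were set against 100 simulated sets of unchanged arrays sharing their controls.

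The rule for naming genes was also fixed before the data were examined. It took the silenced gene, then up to 15 single-symbol genes per direction past the threshold with all 3 shRNA arrays on 1 side of both controls. Where fewer passed, it filled each direction to 10 genes with the smallest unadjusted p among differences of at least 1 log2 unit. It also took the 4 members with the smallest p from each list that passed and from the lists of TIP-1 partners, Wnt targets, invasion proteases and cell cycle, and the brightest markers of other cell types. Alternatives were quantile normalization, median centring, a filter on dim rows, another variance model, array weights, a fold minimum, single-symbol rows only, the replicate number as a block, another row per gene, and leaving out each array. The labels give no batch or date, so no batch could be examined.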

Results

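Gene expression was compared between D54 cells carrying a control shRNA (2 arrays from independent clones) and D54 cells in which TIP-1 was silenced (3 arrays, each with a different shRNA). D54 is an established human glioma cell line. TIP-1 is a small protein made up of a single PDZ domain, a fold that binds the ends of other proteins, and its gene is TAX1BP3. Each array gave 33297 log2 signals, with array medians of 7.96 and 7.98 for the controls and of 7.95, 7.90 and 7.88 for shRNAs 1, 2 and 3. The arrays were alike as a whole, with Pearson correlations across rows from 0.991 to 0.997. The closest pair was shRNA 1 and shRNA 2, where the SD of the differences was 0.191 log2 units. The SD between the 2 controls was 0.252, larger than the 0.212 between control 1 and shRNA 1. Between 1 and 7 rows held identical values in any pair of arrays, so no array was a copy of another.

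The silenced gene was examined first. The row annotated to TAX1BP3, and to the read-through transcript P2RX5-TAX1BP3 that spans it and its neighbour P2RX5, fell by 2.42 on the log2 scale in the TIP-1 shRNA arrays (SE 0.105, 95% interval -2.67 to -2.16, limma adjusted p = 0.011), a 5.35-fold reduction. Its log2 signal was 12.08 ± 0.04 (SD, n = 2) in the controls and 9.66 ± 0.13 (SD, n = 3) with TIP-1 shRNA. The 3 shRNAs gave 9.81, 9.61 and 9.55, so their spread was far smaller than the reduction. The row annotated to P2RX5 and the same read-through transcript did not pass the test, with a difference of 0.09 (SE 0.14, adjusted p = 0.87). It was 1 of 11 rows of genes within 200 kb, whose differences lay between -0.17 and 0.32, none past the threshold. The call on TAX1BP3 needs most of the arrays: without control 1, control 2 or shRNA 2 the log2 difference was -2.45, -2.39 and -2.39, but the limma adjusted p became 0.386, 0.387 and 0.129.

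Across all rows, TAX1BP3 was the only transcript past the threshold, with 0 rows higher and 1 lower (limma, adjusted p under 0.05). At an unadjusted p under 0.05 there were 1000 higher and 1315 lower rows, 2315 in all against 1665 expected by chance. Of the other 9 splits of the 5 arrays into 2 and 3, 2 gave more such rows, 3181 with shRNAs 2 and 3 set apart and 2540 with control 2 and shRNA 3 set apart. The next-lowest adjusted p was 0.124, shared by TNFSF4 and LRATD2. TNFSF4 encodes OX40 ligand, a co-stimulator of T cells, and its signal was 7.49-fold higher with TIP-1 shRNA (log2 difference 2.90, SE 0.23, 95% interval 2.36 to 3.45). It read 7.31 and 7.75 in the controls and 10.76, 10.45 and 10.08 with shRNAs 1, 2 and 3. LRATD2 was 2.93-fold higher (log2 difference 1.55, SE 0.12). Neither passed the test, although TNFSF4 did with array weights (adjusted p = 0.043), a setting that gave shRNA 3 the lowest weight.

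The other 8 genes named on the higher side also missed the threshold, each at an adjusted p of 0.707. Their arrays with TIP-1 shRNA all lay above both controls. They were RPS6KA2, a kinase downstream of ERK (3.83-fold), DIRAS3, a growth-inhibiting Ras-like GTPase (3.01-fold), the cadherin CDH11 (2.86-fold), the desmosome protein DSP (2.54-fold), the homeobox factor MEIS1 (2.27-fold), the hexokinase relative HKDC1 (2.26-fold), the collagen-binding integrin chain ITGA11 (2.16-fold) and the lysosomal transporter SLC46A3 (2.06-fold). The controls themselves differed for DSP, at 6.48 and 8.62, and for CDH11, at 8.67 and 7.57. The log2 difference of DSP, 1.34 with all arrays, was 0.28 without control 1 and 2.41 without control 2, and that of CDH11, 1.52 with all arrays, was 0.97 without control 2. ITGA11 and MEIS1 were called when shRNA 3 was left out (limma adjusted p = 0.0415 for both), with differences of 1.54 and 1.47.

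On the lower side, none of the 10 genes named by the rule passed, and all had each TIP-1 shRNA array below both controls. VEPH1 was 2.28-fold lower (log2 difference -1.19, SE 0.10, limma adjusted p = 0.133) and DIPK1A 2.31-fold lower (-1.21, SE 0.11, adjusted p = 0.203). The other 8 had an adjusted p of 0.707. Among them were matrix and guidance proteins, namely fibronectin FN1 (3.18-fold lower), osteopontin SPP1 (log2 difference -1.32), the axon guidance ligand SLIT2 (2.45-fold) and ADAMTSL1 (2.02-fold). The rest were the Toll-like receptor relative CD180 (2.30-fold), the synaptic adhesion protein NLGN1 (2.24-fold), the cystine and glutamate exchanger SLC7A11 (2.15-fold) and the protein kinase A inhibitor PKIA (2.03-fold). FN1 differed between the controls, at 9.16 and 10.60, and its log2 difference of -1.67 was -0.95 without control 2. SLIT2 differed from the control mean by -1.37, -2.22 and -0.29 in shRNAs 1, 2 and 3, and its log2 difference of -1.29 was -0.83 without shRNA 2. A second ADAMTSL1 row gave a difference of -0.87 (SE 0.18).

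**Figure D1:**
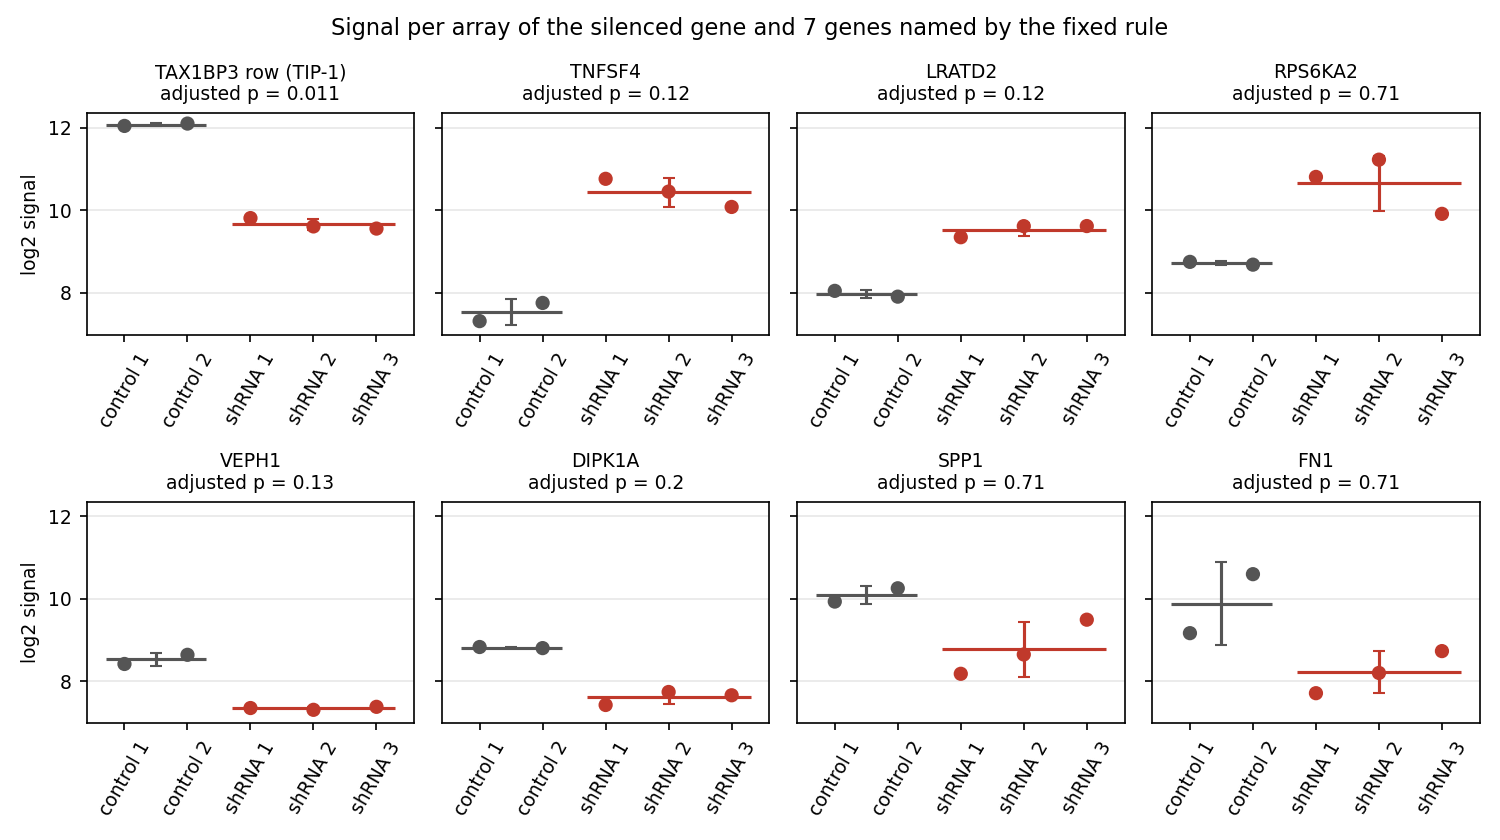
Log2 signal (y axis) in each of the 5 arrays (x axis) for the TAX1BP3 row and 7 genes named by the fixed rule, with controls in grey and TIP-1 shRNAs in red. Horizontal lines are group means and error bars are 1 SD (n = 2 and n = 3); the TAX1BP3 row drops from 12.08 to 9.66 and is the only one past the threshold.

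Of the 31 gene lists, 1 passed camera. Genes of cholesterol synthesis and its control were higher with TIP-1 shRNA (mean log2 difference 0.19, median 0.18, 19 genes, camera adjusted p = 5.08e-05), but not with an estimated correlation (adjusted p = 0.847). Of the 19, 17 were higher and 2 lower, and 11 had all 3 shRNA arrays above both controls. None passed over all rows, and none passed when adjusted over the list alone (smallest adjusted p = 0.131). The members with the smallest p were MSMO1, a sterol oxidase (1.37-fold, 95% interval of the log2 difference 0.14 to 0.78), INSIG1, which retains the sterol sensor in the endoplasmic reticulum (1.52-fold, 0.17 to 1.03), mevalonate kinase MVK (1.15-fold) and lanosterol synthase LSS (1.18-fold). The list's median difference from the controls was 0.12 in shRNA 1, 0.17 in shRNA 2 and 0.25 in shRNA 3. The call was lost without control 2 (adjusted p = 0.228).

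**Figure D2:**
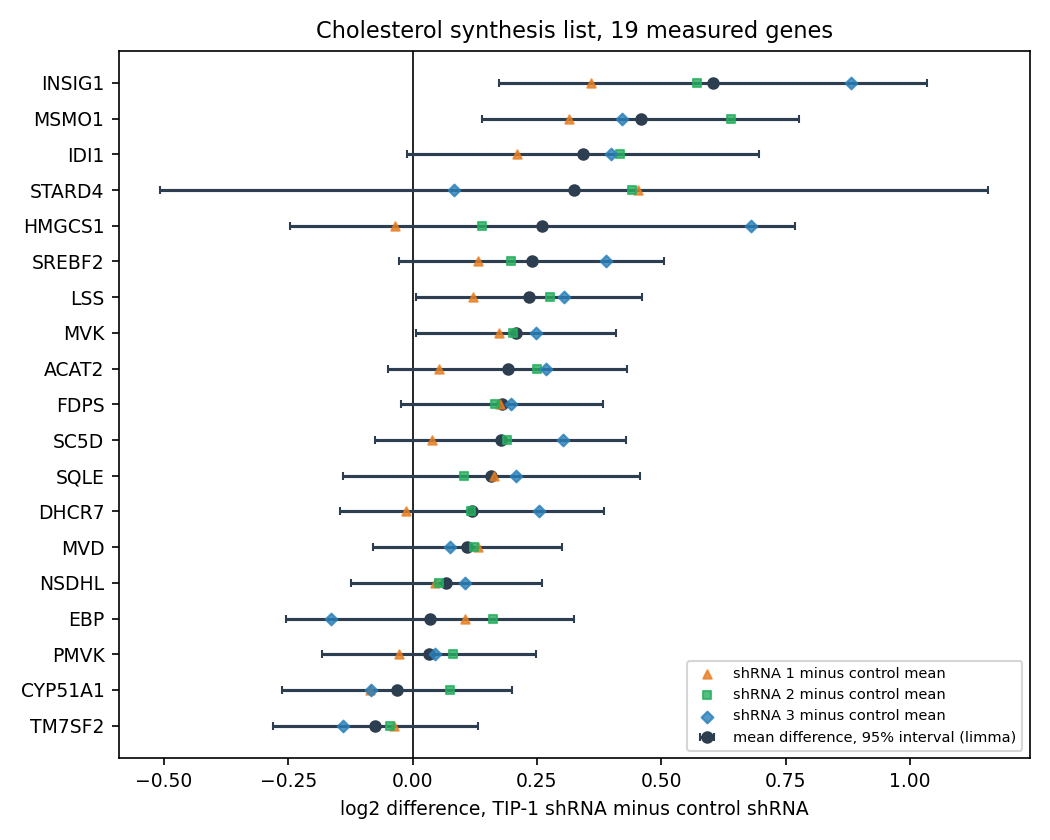
Log2 difference from control (x axis) for each of the 19 measured genes of the cholesterol synthesis list (y axis). Dark circles are the mean of the 3 shRNAs with limma's 95% interval and coloured symbols are single shRNA arrays minus the control mean; 17 means lie above 0, and INSIG1 has the highest, at 0.60.

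No fry test passed for any list after adjustment, in 1 direction or mixed. The interferon response list came next in camera (mean log2 difference -0.12, 38 genes, adjusted p = 0.115), with 26 members lower and 12 higher. Its members with the smallest p, chosen after their values were seen, were IFI44L (-0.46, SE 0.10) and IFI44 (-0.81, SE 0.21), and neither passed. The mean was -0.07 without shRNA 1 and -0.08 without shRNA 2. With quantile normalization the list did not pass (mean -0.09, camera adjusted p = 0.220). Without shRNA 3 it passed (mean -0.21, camera adjusted p = 1.74e-05), and it also passed after median centring, though with a mean nearer zero (-0.06, camera adjusted p = 0.027). With an estimated correlation it passed in neither (camera adjusted p = 0.866 and 0.971), nor with all arrays as deposited (0.847).

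Transcripts of the known partners of TIP-1 were measured for 6 genes, and none passed over all rows or adjusted over the list alone (camera adjusted p = 0.389). The death receptor FAS differed by -0.47 (95% interval -0.96 to 0.02), the potassium channel KCNJ4 by -0.19, the exchange factor ARHGEF16 by -0.17 and RTKN by -0.09. FAS read 8.92 in shRNA 3, between the controls at 9.14 and 8.88. With 1 array left out, its difference was -0.66 without shRNA 3 and -0.34 without shRNA 1 or control 1. KCNJ4 came to -0.12 without shRNA 3, and RTKN lay between -0.17 (without control 1) and -0.01 (without control 2). Beta-catenin, CTNNB1, differed by 0.00 (-0.24 to 0.25), and the exchange factor ARHGEF7 by 0.04 (-0.17 to 0.25). These 2 were named after their values were seen.

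The Wnt/beta-catenin target list had a median of 0.03 over 25 genes (camera adjusted p = 0.538). Its members with the smallest p were the transcription factors SP5 (-0.24, SE 0.09) and FOSL1 (-0.20, SE 0.10), the protease MMP7 (0.22, SE 0.10) and the receptor LGR5 (0.64, SE 0.33, but 0.29 without shRNA 3). Among 40 invasion proteases and inhibitors the median was -0.01 (camera up, adjusted p = 0.970). MMP15 (0.30, SE 0.08), ADAM23 (-0.47, SE 0.14), ADAM15 (-0.26, SE 0.10, but -0.16 without control 2) and ADAM8 (-0.29, SE 0.11) had the smallest p. The 45 cell cycle genes had a median of -0.03 (adjusted p = 0.970), and the leading members were MCM6 (0.22, SE 0.09), CCNB1 (-0.21, SE 0.12, but -0.12 without shRNA 2), TPX2 (-0.14, SE 0.08) and GINS2 (0.14, SE 0.09, but 0.08 without control 1). No member of these 3 lists passed over all rows or adjusted over its list alone.

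Over all lists, 3 members passed when adjusted over their list alone, all named after their values were seen. In the inflammatory list (median -0.03), the chemokine CXCL8 was lower (-0.54, SE 0.09, limma adjusted p over the list 0.026) and the cytokine LIF higher (0.60, SE 0.12, 0.036). In the immediate early list (median 0.02), the growth factor signalling inhibitor SPRY2 was higher (0.92, SE 0.16, 0.034). All 3 had an adjusted p of 0.707 over all rows. The remaining lists described here all had a camera adjusted p of 0.389 or above. Their median differences were 0.09 for TGF-beta targets (mean -0.01), 0.06 for p53 targets, 0.04 for other PDZ domain proteins and 0.04 for the RNA interference machinery. They were 0.02 for ribosomal proteins, 0.00 for apoptosis genes (mean -0.00) and 0.00 for mesenchymal glioblastoma markers. They were -0.01 for integrins and adhesion receptors (mean 0.08), -0.02 for hypoxia and glycolysis, -0.02 for endoplasmic reticulum stress and -0.03 for YAP/TAZ targets. They were -0.05 for actin and myosin, -0.06 for proneural markers and -0.08 for extracellular matrix. The sign of the median, the mean and camera differed for several lists: camera pointed up for the lists of TGF-beta targets, integrins, astrocytes, YAP/TAZ targets, apoptosis and proteases, each with a negative median or mean, and down for fibroblast markers (mean 0.01) and the inflammatory list (mean 0.02).

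Markers of other cell types were not higher in either group by the test. Median differences were -0.10 for oligodendrocytes, -0.08 for microglia and macrophages, -0.06 for epithelium, -0.06 for fibroblasts, -0.05 for neurons, -0.05 for endothelium and -0.03 for astrocytes, with camera adjusted p from 0.389 to 0.945. The array medians were also lower with TIP-1 shRNA (7.95, 7.90 and 7.88 against 7.96 and 7.98), and these differences were not corrected for that. The brightest members, KRT8 (13.38 in controls and 13.50 with TIP-1 shRNA), CD68 (12.58 and 12.50), ENG (12.35 and 12.32), THY1 (12.10 and 11.94), NEFL (12.06 and 12.02), CLU (12.01 and 12.14) and CNP (11.67 and 11.70), did not pass the test.

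The agreement of the 3 shRNAs was examined because they differ in sequence; each had 1 array, so these values carry no test. Of all rows, 26.1% had the 3 shRNA arrays all above or all below both controls (3858 above, 4826 below), against the 20% that the 10 splits of the arrays into 2 and 3 average by construction. The other 9 splits gave 14.0% to 30.02%, the highest with shRNAs 2 and 3 set apart, so the real split did not give the highest share. In all 3 shRNA arrays at once, 8 rows were at least 2-fold above the control mean and 4 at least 2-fold below, against 1.95 and 2.03 in simulated unchanged arrays sharing the controls. The simulation may understate the effect of shared controls. Its covariance between shRNAs was 0.012, against 0.016 estimated from the real controls. The 4 lower rows were TAX1BP3, FN1, VEPH1 and DIPK1A. The 8 higher rows were TNFSF4, RPS6KA2, SYTL5, LRATD2, DIRAS3, CDH11, DSP and HKDC1. SYTL5, named here as part of that count, read 6.21 in control 2 and between 9.57 and 10.15 in the other 4 arrays. The controls also differed for DSP, at 6.48 and 8.62.

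shRNAs 1 and 2 resembled each other more than either resembled shRNA 3. Across rows, which are not independent replicates, the differences from control correlated at r = 0.620 for shRNAs 1 and 2, 0.227 for 1 and 3, and 0.373 for 2 and 3, against 0.335 in simulated unchanged arrays. The covariances were 0.029, 0.013 and 0.025 against a simulated 0.012. Minus the 0.016 estimated from the difference between the controls, they came to 0.013, -0.003 and 0.009. The 2 controls could not be split, so part of any excess may come from sharing them. At 2-fold, shRNAs 1 and 2 shared 32 higher and 40 lower rows, against 5.86 and 5.49 simulated and 0.094 and 0.191 for independent lists. shRNA 1 shared 10 and 6 rows with shRNA 3, and shRNA 2 shared 21 and 10. Over rows with 1 gene symbol these were 9 and 5 for shRNA 1 and 8 and 4 for shRNA 2. In total 104 rows differed 2-fold from the control mean in shRNA 1, 177 in shRNA 2 and 247 in shRNA 3. Among rows with 1 gene symbol, 32, 31 and 102 were higher and 46, 50 and 30 lower, so shRNAs 1 and 2 were closer there.

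**Figure D3:**
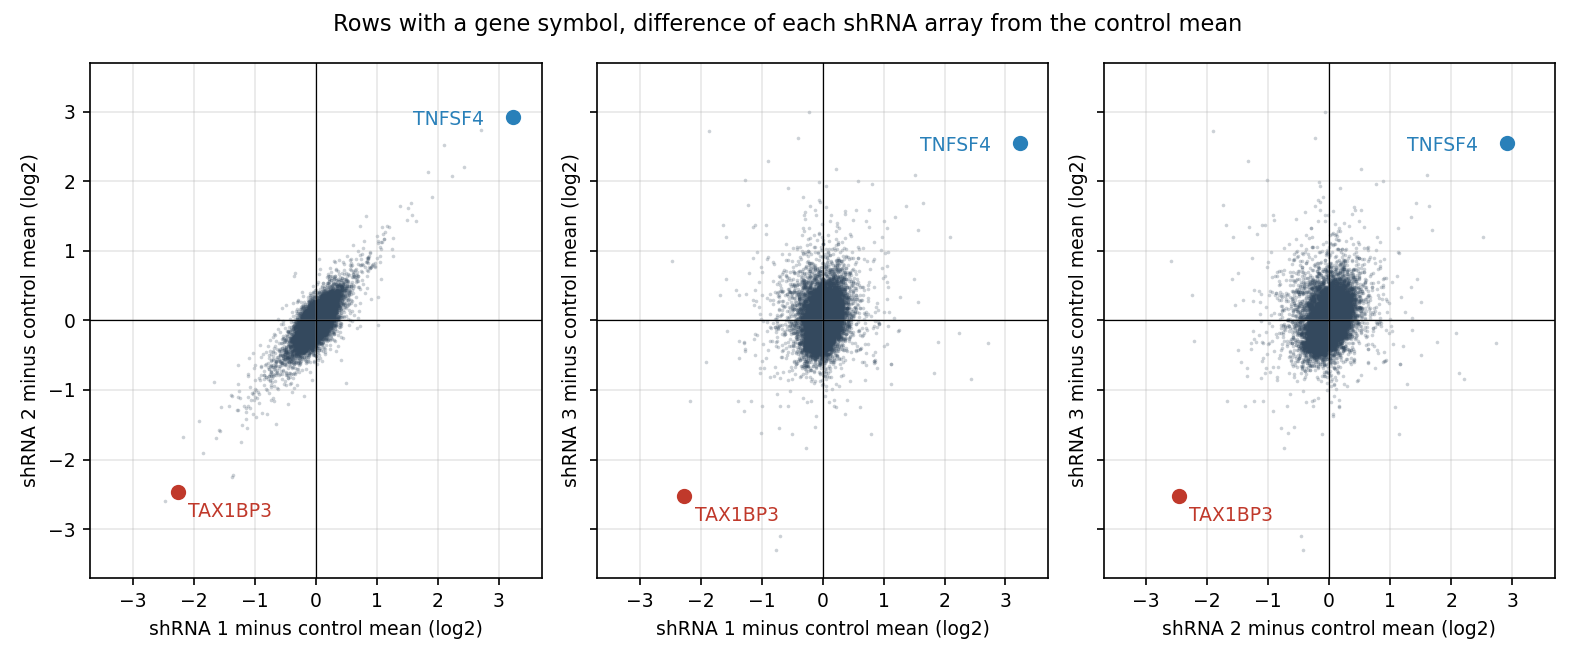
Difference of each shRNA array from the control mean in log2 units, shRNA against shRNA in 3 panels, for the 21214 rows with a gene symbol (points). Points lie along the diagonal for shRNAs 1 and 2 (r = 0.620 over all rows) and form a rounder cloud for pairs with shRNA 3. TAX1BP3 (red) and TNFSF4 (blue) lie far from the origin in every panel. In the panel of shRNAs 1 and 2, ANXA3 (-2.47 and -2.60) lies near TAX1BP3 and CD24 (2.70 and 2.73) near TNFSF4.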

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

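TAX1BP3 was lower in every alternative run, and it passed with quantile normalization (-2.45), median centring (-2.36), bright rows only, the trended robust fit and the replicate block (-2.37). Leaving out 1 array gave -2.495 to -2.37; the call was lost without control 1, control 2 or shRNA 2 (adjusted p 0.386, 0.387 and 0.129). Without a control, the lone control is assumed to vary like the shRNA arrays. The number of rows past the threshold was 1 as deposited, with quantile normalization, median centring, bright rows only, the trended robust fit and the fold minimum, 0 to 6 when 1 array was left out (0 without control 1, control 2 or shRNA 2, 2 without shRNA 1, 6 without shRNA 3), 2 with array weights, and 0 with single-symbol rows only, since the TAX1BP3 row carries 2 symbols. With the replicate block it was 15 (8 higher, 7 lower), among them TNFSF4, RPS6KA2, MEIS1, ITGA11 and SPP1; this fit leaves shRNA 3, which has no partner, out of the difference. Arrays sharing a number deviated together at r = 0.049 for number 1 and -0.053 for number 2, so the numbers were not taken as pairs. The number of lists past camera was 1, but 2 with median centring, 2 with the replicate block, 0 with an estimated correlation, and 0 to 2 when 1 array was left out (0 without control 2, 2 without shRNA 3); the added list was always the interferon response. The cholesterol list had an adjusted p of 0.847 with an estimated correlation and of 1.73e-06 to 0.228 when 1 array was left out. The share of rows with separated groups was 26.1%, 25.8% among bright rows and 24.2% after quantile normalization. Near-zero list means changed sign: to 0.0536 for proteases and 0.0509 for cell cycle with median centring, which raises all differences alike, to 0.00522 for proteases with quantile normalization and 0.0117 with another row per gene, and to 0.0132 for proteases and 0.0155 for cell cycle with the block. Leaving out 1 array gave means of -0.035 to 0.020 for proteases and -0.039 to 0.019 for cell cycle. Besides TAX1BP3 and the cholesterol list, whose lost calls are given above, named genes and lists had 453 values, of which 433 kept direction and side of the threshold, 10 changed sign (those 2 lists) and 10 became calls. Array weights, the fold minimum and single-symbol rows only were left out of that tally. With array weights TNFSF4 also became a call (limma adjusted p = 0.043). The cause was not tested beyond what is stated. The table gives no background signal, so limits for dim rows are unknown.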

Other observations

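The tests on array noise, on the splits for the row past the threshold and of the NRF2 list over the real groups, and the choice of that list, came after the related values had been seen, as did the choice of the genes named here. When shRNA 3 is set aside, shRNAs 1 and 2 shared features that it lacked: 12 named rows at least 2-fold higher and 15 lower in both, with shRNA 3 within 0.5 log2 units of the control mean, though the controls themselves differed for some (ARHGDIB read 7.62 and 9.39). The higher ones included the surface glycoprotein CD24 (10.21 and 10.24, against 7.98 and 7.02 in the controls and 7.18 in shRNA 3), the protocadherin PCDH7 (11.03 and 10.90 against 9.20, 9.05 and 8.81) and the transcription factor KLF4 (differences of 1.06 and 1.05 from the control mean, with 7.87 and 8.02 in the controls and 7.60 in shRNA 3). The lower ones included smooth muscle actin ACTA2 (8.98 and 9.12 against 10.25, 10.21 and 10.61) and the laminin chain LAMB3 (differences of -1.29 and -1.10 against -0.32 in shRNA 3). For shRNA 3 alone, only rows whose controls lay less than 0.5 apart were counted. Of these, 12 named rows were at least 1.5 log2 units higher, with the other shRNAs within 0.5, and 0 lower. They included the selenium carrier SELENOP (8.94 against 5.73 to 6.04 elsewhere), ZNF385D (8.81 against 5.78 to 6.35) and the GABA receptor subunit GABRA3 (a difference of 1.99). These rows were picked for their pattern, with 1 array per shRNA, and carry no test.

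Other rows parted the 2 groups by a clear gap without passing the test, in addition to those already described. The receptor phosphatase PTPRB read 8.30 and 8.44 in the controls and 9.21 to 9.26 with TIP-1 shRNA (limma adjusted p = 0.213), interleukin IL18 8.73 and 8.79 against 9.49 to 9.56 (0.265), and the methyltransferase NNMT 9.11 and 8.88 against 9.77 to 10.05 (0.597). In all, 51 rows had groups at least 0.5 log2 units apart. Among the 10 splits of the 5 arrays into 2 and 3, 4 gave at least as many such rows, the real one included. The others gave 139 with shRNAs 1 and 2 set apart, 113 with control 2 and shRNA 3, and 72 with shRNAs 2 and 3. Of these, 104, 80 and 5 had 1 gene symbol, against 29 of the 51 in the real split. Among rows with 1 gene symbol, setting shRNAs 2 and 3 apart thus gave fewer than the real split. Silencing that acted more in 2 of the shRNAs could add to the splits that set 2 shRNAs apart, so those cannot stand for unrelated groupings. The TAX1BP3 row itself differed from the control mean by -2.27, -2.47 and -2.52 in shRNAs 1, 2 and 3. By transcript level, with 1 array each, silencing was thus not stronger in shRNAs 1 and 2, whose split gave 139. For rows past the threshold, 4 of the 10 splits, the real one included, gave at least the real 1, and the highest of the others gave 8. With 10 splits no share can fall under 0.05.

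The split with 8 rows past the threshold set control 2 and shRNA 3 against the other arrays, which points to a structure in some rows other than silencing, although across all rows these 2 arrays were the least alike pair (SD of differences 0.315). Among rows picked for this pattern, CYB5A, cytochrome b5, read 6.07, 6.04 and 6.00 in control 1 and shRNAs 1 and 2, but 9.73 in control 2 and 10.63 in shRNA 3. PCDHB5 read 6.26, 6.21 and 6.16 against 9.44 and 9.23, and the cytidine deaminase CDA 8.26, 8.71 and 8.54 against 11.44 and 11.19. Symmetric noise of the shRNA 3 array as the whole cause is argued against, since named rows 2-fold from the control mean were 3.4 times as often higher as lower in it (102 against 30), while unannotated rows were even (55 against 55). The sources used here say that the controls were independent clones but not whether the TIP-1 shRNA cells were clones or pools, and no biological explanation was tested.

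The cholesterol synthesis list was higher with TIP-1 shRNA by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.847) or by fry (adjusted p = 0.595). A shift of bright rows between the arrays is argued against: the list's mean of 0.19 lay at percentile 99.9 of 10000 random lists matched on signal level, whose median was 0.03 and whose central 95% ran from -0.05 to 0.11. The list was chosen because it passed camera on these values, and its genes were correlated (estimate 0.27). The percentile therefore compares signal levels and is too extreme as a measure of chance. If its genes move together whatever the group, other splits should pass too, and in 2 of the other 9 the list passed camera. With control 2 and shRNA 1 set apart, the list was lower in those 2 (camera adjusted p = 4.22e-05, against the real 5.08e-05). Each side of that split held both groups. With shRNAs 2 and 3 set apart, it was higher in those 2 (camera adjusted p = 2.54e-05). That split cannot tell the explanations apart, because silencing that acted more in shRNAs 2 and 3 would also make it pass. The list may therefore follow the state of each culture rather than silencing, and these cannot be separated with 5 arrays.

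Among the genes furthest below the controls in shRNA 3, beside IGFBP3 (10.24 against 12.09 and 12.05) and SUCNR1, were the aldo-keto reductases AKR1C2 (7.03 against 11.22 and 9.44 in the controls), AKR1C1 (7.07 against 10.86 and 9.48, and 7.39 against 8.19 and 8.08 in another row) and AKR1C3 (6.39 against 8.40 and 7.65), together with SLC7A11 (8.44 against 9.91 and 10.23). Probes of these closely related AKR1C paralogs may cross-hybridise. The AKR1C genes and SLC7A11 are known targets of the oxidative stress factor NRF2. As a hypothesis, lower NRF2 activity was tested on 24 other target genes listed before their values were seen: their mean difference in shRNA 3 was -0.14, at percentile 0.02 of level-matched random lists, which covers the choice of genes but not the spread between arrays. The list was also low in shRNA 1 (-0.11, percentile 0.14) and shRNA 2 (-0.07, percentile 2.31), and its medians of -0.14 in both were below the -0.12 in shRNA 3, so it did not set shRNA 3 apart and the hypothesis stays open. All 3 differences share the same 2 controls, so part of this likeness may come from them. Over the real groups its camera p was 0.00034 at the preset correlation and 0.029 with an estimated one, but 3 of the other 9 splits also gave a camera p under 0.05 (smallest 0.000185), and the NRF2 target HMOX1 read 12.35 and 12.38 in shRNAs 1 and 2 and 10.90 in shRNA 3, against 11.46 and 11.52 in the controls.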
